A study of Homo sapiens with 6 samples.

How the data were processed

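Total RNA of 22Rv1 cells, isolated with TRIzol, was sequenced in 6 libraries, 2 each of WT, KO and MUT cells, grouped by the genotype and the replicate number in the sample labels. The submitters' processing notes name HISAT2, HTSeq and DESeq2 and the genome build hg19, without versions, and do not state how these were used. The values deposited by the authors are TPM for 57773 genes, as each of the 6 columns sums to 1000000; the WT and KO values carry 6 decimals and the MUT values 2. The sample labels give no batch, so a difference in sequencing or processing between MUT and the other groups could not be separated from the edit. The table held no other value column. How the authors computed the TPM, the gene annotation and the strand setting are not stated. TPM keep no read totals, so the depth of each library is unknown and no counting intervals were computed. The titles give replicate numbers, and the fits treated the libraries of a group as replicates without a block.

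Gene types, lengths and chromosome order came from GENCODE release 29, in which 90.6% of the gene identifiers were found. That release is on another build than the deposited values, so only the order of genes was used and no coordinates are given. The small structured RNAs are 7412 genes taken by name alone, among them snRNA, snoRNA, 7SK, 7SL and Y RNA genes with their pseudogenes. Some protein-coding genes matched the name pattern as well. The share of the set is a share of TPM, which gives short RNAs more weight per read. The 103 structured RNA genes of up to 166 nt in the length comparison were all at 0 in both MUT libraries, and whether a length limit was set in processing is not stated.

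The values were analysed on the scale of log2(TPM + 1) without rescaling. The 17664 genes at 1 TPM or more in at least 2 libraries were tested with limma 3.58.1 in R 4.3.3, with a coefficient for each of the 3 groups, moderated variances with a trend, two-sided moderated tests and Benjamini-Hochberg adjustment over all tested genes. A gene passed at an adjusted p under 0.05, with no minimum fold. The 31 gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 30 lists with at least 5 tested members, the leukocyte markers having too few; an estimated correlation and fry were computed beside it. Counts for a list are given over all tested genes and adjusted over the list alone. The tests, their main settings, the alternatives not named as added, the gene lists and the rule for named genes were chosen before the data were examined.

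Named genes followed a rule. In each comparison with WT these are the genes of the JAZF1 and HOXA neighbourhood; the 8 largest increases and the 8 largest decreases among genes that passed, had a group mean of at least 5 TPM and did not overlap between groups; up to 4 members with the smallest p of each list that passed, of the androgen-induced genes and of the lineage transcription factors, with FOXA1, HOXB13 and MYC always; and up to 5 genes per direction called in both comparisons. In MUT minus KO the rule named 5 per direction. The largest decreases by this rule were mostly U1 RNA copies, so the same rule was applied to protein-coding values as well; the genes this added, among them ECM1, ANXA2, SLITRK6, SPOCK1, ANKRD30BL, HBE1, SSX3, NEFH and HAVCR1, were chosen after their values were seen, as was HOXA10-AS in MUT.

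The alternatives were pseudocounts of 0.1 and 0.5, no filter on low values, a minimum of 5 TPM, median-ratio rescaling of the libraries over genes with a mean of at least 5 TPM, quantile normalization, no variance trend, robust empirical Bayes, only the 2 compared groups in the fit, the replicate number as a block, each library left out in turn, an absolute log2 fold change of at least 1, and camera with an estimated correlation. Added after the data were seen were protein-coding genes rescaled to 1000000 TPM, median-ratio rescaling of protein-coding genes with a loess correction for length (span 0.5), and median-ratio rescaling together with each library left out, with only the compared groups and with the block. Lists that passed only after rescaling entered the list counts with a library left out, but their single results there are not given. Where a library was left out, the lone library of its group was assumed to vary like the others. Groups of 2 libraries allow no outlier rule and no count of other splits.

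For the overlap of the comparisons with WT, 100 simulated pairs of unchanged groups were set against the same WT libraries. For the chromosome profiles, the rescaled log2 fold changes of 12423 protein-coding genes were taken relative to their median, averaged in windows of 25 neighbouring genes, and set against the highest and lowest window in 1000 shuffles of the gene order; the plotted lines are running medians over 21 genes. The bounds of the chromosome segments were chosen after the profiles were seen, so their values are descriptive. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

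The tests were checked on simulated data for KO minus WT, in which 200 of 17664 genes were changed. As deposited 7% of changes of 1 and 72% of changes of 2 on the log2 scale were recovered, with 0 unchanged genes called; after median-ratio rescaling 47% and 97% were recovered, with 13 unchanged genes called. A shifted gene list was found as deposited (camera adjusted p = 7.51e-09) and 0 of the other lists passed. The simulated genes varied independently, so the list test was not checked against correlation between genes. No shift of whole libraries was simulated either. The 0 unchanged genes called as deposited thus do not cover calls that come from the composition of the libraries. In simulated chromosome windows 30 lay below the lower limit, all over shifted genes, and 0 lay outside the limits without a shift.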

Results

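RNA was sequenced from 22Rv1, a human prostate cancer cell line, in 3 groups of 2 libraries each. WT cells were compared with cells labelled as a knockout of rs10486567 (KO) and with cells labelled as carrying a homozygous G-to-A change at the same variant (MUT). The variant is associated with prostate cancer risk and lies in an intron of JAZF1, a zinc finger gene next to the HOXA cluster on the short arm of chromosome 7. The comparisons address which genes differ when the site is removed, which differ when its base is changed, and whether the 2 edits differ from each other. The deposited table gave length-scaled shares of transcripts (TPM) for 57773 genes, of which 17664 reached 1 TPM in at least 2 libraries and were tested. The sequencing depth is unknown because TPM keep no read totals. Nothing in the labels says that the replicates came from separate cultures, so every p-value measures only the spread between these libraries.

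The composition of the libraries differed between the groups. Small structured RNAs, such as 7SK, the signal recognition particle RNAs and the RNA of RNase MRP, took 42.2% ± 1.33 (SD, n = 2) of all TPM in WT, 60.5% ± 1.17 in KO and 76.4% ± 8.01 in MUT. Within MUT the share was 82.1% in replicate 1 and 70.8% in replicate 2. RN7SL1, an RNA of the signal recognition particle, took 10.5% ± 2.76 in WT, 17.003% ± 1.98 in KO and 26.8% ± 0.109 in MUT. RMRP, the RNA of RNase MRP, took 2.32% ± 0.297, 7.37% ± 0.816 and 6.70% ± 1.37 in the same order. Protein-coding genes held 44.9% ± 0.212 in WT, 31.5% ± 0.501 in KO and 19.3% ± 8.15 in MUT, and mitochondrially encoded genes held 8.10% ± 0.850, 4.78% ± 0.611 and 2.02% ± 0.699. The number of genes at 1 TPM or more was 17826 and 17643 in WT, 15474 and 15198 in KO, and 11666 and 14828 in MUT. Spearman correlations between the replicates, across genes, were 0.970 in WT, 0.966 in KO and 0.946 in MUT.

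**Figure D1:**
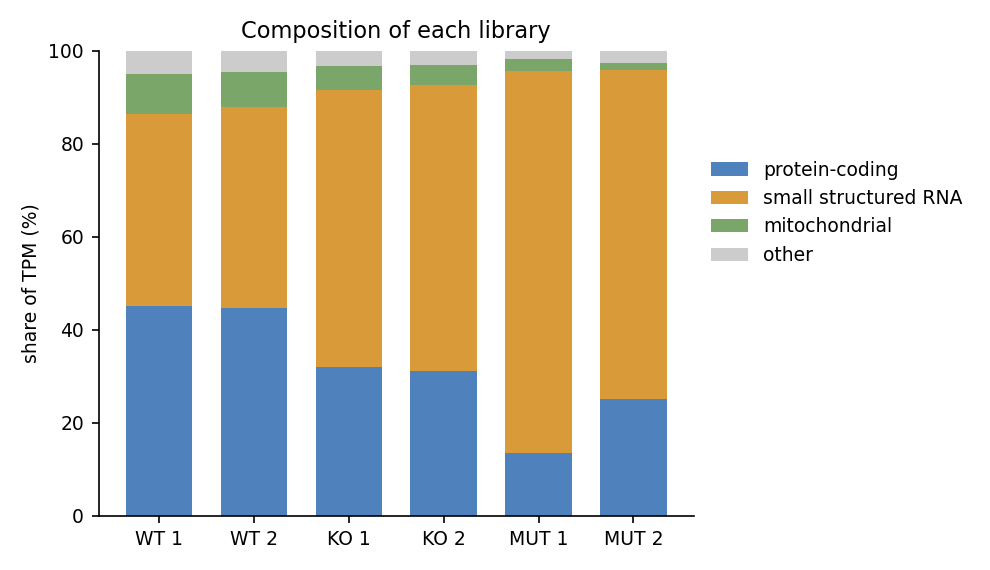
Stacked bars give the share of TPM, in percent, held by protein-coding genes, small structured RNAs, mitochondrial genes and all other genes in each of the 6 libraries. Protein-coding genes held 45.1% and 44.8% in the WT libraries and 13.5% and 25.1% in the MUT libraries, where small structured RNAs took the larger share.

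Because TPM share a fixed sum, a larger share for a few RNAs lowers every other gene. The median log2 fold change over all tested genes was -0.51 in KO minus WT, -1.11 in MUT minus WT and -0.58 in MUT minus KO. Values rescaled by the median ratio of expressed genes, for which these medians were -0.01, -0.02 and -0.01, are therefore given beside the deposited ones. Fold changes are on the scale of log2(TPM + 1), which understates those of low genes.

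At the edited locus, JAZF1 (ENSG00000153814) measured 6.58 and 6.39 TPM in the WT libraries, 2.69 and 2.45 TPM in KO, and 1.18 and 3.02 TPM in MUT. In KO its log2 fold change against WT was -1.07 (SE 0.43, adjusted p = 0.128, or 0.0310 adjusted over the list alone), and after rescaling it was -0.56 (SE 0.18, adjusted p = 0.125). JAZF1 passed in KO with only the compared groups in the fit (adjusted p = 0.00907), and also without MUT replicate 1 or 2. With only the compared groups, however, 7631 of the 17664 tested genes fell as deposited. After rescaling 0 of the risk locus genes passed in that fit. In MUT the log2 fold change of JAZF1 was -1.34 (SE 0.43, adjusted p = 0.0126), but -0.29 after rescaling (SE 0.18, adjusted p = 0.341). JAZF1 also did not pass in MUT without WT replicate 1 (adjusted p = 0.164) or WT replicate 2 (0.143). Its antisense gene JAZF1-AS1 was listed at 0 in all 6 libraries, and EVX1, EVX1-AS and HOTTIP were too low to test.

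Around JAZF1 in KO, 4 of the HOXA genes, which encode homeobox factors of body patterning, fell against WT as deposited and 0 after rescaling. HOXA7 fell by 1.67 on the log2 scale (SE 0.38, adjusted p = 0.00230), from 4.97 ± 2.26 to 0.814 ± 0.130 TPM (SD, n = 2). HOXA3, HOXA4, HOXA9, HOXA10-AS and CREB5 also fell, with log2 fold changes from -1.04 to -1.40. Of the 19 tested genes of the risk locus list, 6 fell, and 15 fell when adjusted over the list alone; after rescaling 0 passed either way. As a group the list stayed below the other genes, with a median log2 fold change of -1.04 as deposited (camera adjusted p = 0.00257) and -0.54 after rescaling (adjusted p = 0.000339). With an estimated correlation the adjusted p was 0.990 as deposited and 0.320 after rescaling. The gene count was 1 without WT replicate 1, 0 without WT replicate 2, 0 and 1 without KO replicate 1 and 2, and 16 without either MUT replicate, and the call of HOXA7 ended without WT replicate 2 (adjusted p = 0.391) or KO replicate 1 (0.0898). With a minimum of 5 TPM the list did not pass (adjusted p = 0.340). The strand setting is not stated, so the values of the HOXA antisense genes are uncertain.

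In MUT, HOXA9 fell from 9.58 ± 0.719 to 0.575 ± 0.177 TPM and HOXA10-AS, which lies in the same part of the cluster, from 6.495 ± 0.483 to 0.125 ± 0.177 TPM. Both passed as deposited (log2 fold changes -2.75 and -2.74, adjusted p = 4.15e-06 and 7.74e-07) and after rescaling (-1.79 and -2.17, adjusted p = 0.0163 and 0.00254). As deposited 15 of the 19 tested genes fell, 15 when adjusted over the list alone, against a median of all genes that was itself -1.11. After rescaling only these 2 fell, over all genes and when adjusted over the list alone, and the list as a whole did not pass the camera test (adjusted p = 0.274 as deposited and 0.287 rescaled). The deposited count was 3 and 2 without WT replicate 1 and 2, and 8 and 9 without KO replicate 1 and 2. After rescaling HOXA9 did not pass without WT replicate 1 (adjusted p = 0.138) or WT replicate 2 (0.105), and HOXA10-AS did not pass without WT replicate 1 (0.0513), so that 0 genes of the list were left there.

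**Figure D2:**
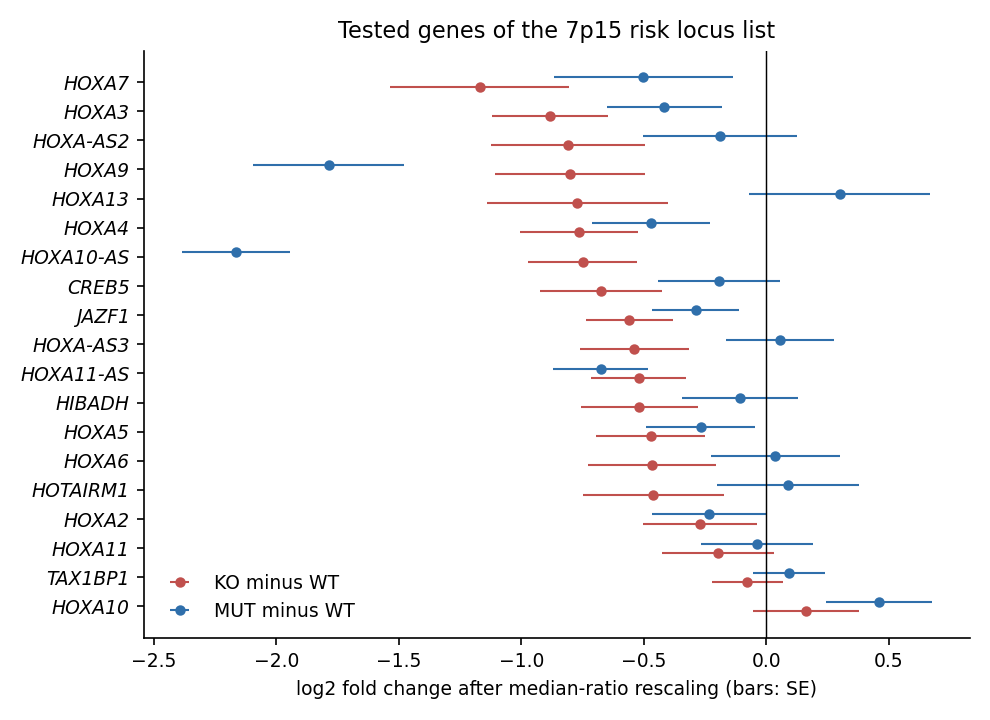
Points are log2 fold changes after median-ratio rescaling, with bars of 1 SE, for the 19 tested genes of the risk locus list in KO minus WT and MUT minus WT. In KO 18 of 19 lie below 0 without passing singly, while in MUT HOXA9 at -1.79 and HOXA10-AS at -2.17 lie apart from the rest; HOXA10 lies above 0 here but below it in the deposited values.

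The largest increases in KO against WT included 4 enzymes that inactivate or convert steroids, a group for which no list was tested. UGT2B15, which glucuronidates androgens, rose from 0.405 ± 0.0773 TPM in WT to 62.8 ± 30.3 TPM in KO (SD, n = 2; log2 fold change 5.42, SE 0.46, adjusted p = 1.64e-11), and UGT2B10, of the same enzyme family, rose by 3.46. The aldo-keto reductases AKR1C2 and AKR1C3, which reduce steroid ketones, rose by 3.84 and 3.33. SPINK1, a secreted trypsin inhibitor, rose from 5.00 ± 2.07 to 94.2 ± 12.6 TPM, and DDC, the decarboxylase that makes dopamine, from 0.647 ± 0.491 to 20.2 ± 9.12 TPM. SYT4, a synaptotagmin of secretory vesicles, rose by 3.47, and MME, the neutral endopeptidase, by 3.23. MME lay in a run of higher genes on chromosome 3, in a window with only 1 of 25 protein-coding genes below the median gene. The UGT2B and AKR1C genes have close paralogs, so the share of reads assigned to each member is uncertain. All 8 also rose after rescaling, although after rescaling DDC did not pass without WT replicate 2 (adjusted p = 0.0673), nor MME without WT replicate 1 or 2 (0.0779 and 0.0854).

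Among protein-coding genes outside chromosome Y, the largest decreases in KO were nearly complete. ECM1, an extracellular matrix protein, measured 106.6 ± 54.7 TPM in WT and 0.145 ± 0.0952 TPM in KO (log2 fold change -6.46, SE 0.45, adjusted p = 1.38e-13). ANXA2, a membrane-binding annexin, fell from 88.2 ± 27.6 to 0.284 ± 0.202 TPM, and SLITRK6, a neuronal transmembrane protein, from 102.1 ± 2.77 to 0.946 ± 0.0371 TPM. PMEPA1, an androgen-induced inhibitor of TGF-beta signalling, fell from 197.3 ± 4.06 to 1.45 ± 0.856 TPM (log2 fold change -6.38, SE 0.52, adjusted p = 5.97e-12), and SPOCK1, a matrix proteoglycan, fell by 4.86. These 5 also fell after rescaling and without any single library. All 10 tested protein-coding genes of chromosome Y fell in KO, and likewise in MUT. The largest decreases of all were copies of the U1 spliceosomal RNA, whose near-identical copies cannot be assigned with certainty: RNU1-2 measured 2121.7 and 2639.7 TPM in WT and RNU1-4 2222.1 and 2655.4 TPM, and both were listed at 0 in both KO libraries, as was SNORD33.

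Among the androgen-induced genes, 2 rose and 13 fell of 68 tested (2 and 19 when adjusted over the list alone), and 2 rose and 7 fell after rescaling (5 and 12 when adjusted over the list alone). Besides PMEPA1, KRT19, a luminal keratin, fell from 60.8 ± 24.5 to 1.39 ± 1.14 TPM and GUCY1A3, a subunit of guanylate cyclase, from 4.82 ± 0.876 to 0.0452 ± 0.0639 TPM. The list as a whole did not pass the camera test (adjusted p = 0.170). Of 22 prostate lineage transcription factors, 5 fell and 0 rose (8 and 0 when adjusted over the list alone; after rescaling 2 rose and 4 fell, or 6 and 7 when adjusted over the list alone), and the list did not pass (adjusted p = 0.927). FOXA1, a pioneer factor that opens chromatin, fell from 260.7 ± 41.8 to 71.9 ± 5.46 TPM (log2 fold change -1.84, SE 0.47, adjusted p = 0.00768; rescaled -1.24, adjusted p = 0.0393). GATA2, SPDEF and TRPS1, further factors of the luminal lineage, had log2 fold changes of -1.75, -1.79 and -2.23 and passed, each also after rescaling. Leaving out 1 library ended the deposited call of FOXA1 for each WT and each KO library (adjusted p from 0.191 to 0.628), and those of GATA2 (0.186 to 0.602), SPDEF (0.177 to 0.513) and TRPS1 (0.0533 to 0.233). MYC, a growth-promoting factor, measured 121.2 ± 15.4 TPM in WT and 60.3 ± 9.89 TPM in KO and did not pass (adjusted p = 0.216). HOXB13 measured 36.4 ± 4.12 and 38.0 ± 3.97 TPM (adjusted p = 0.940).

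In all, 1615 genes passed in KO minus WT, 142 higher and 1473 lower, and after rescaling 1143 passed, 418 higher and 725 lower; 802 passed both ways in the same direction. The count was 330 without WT replicate 1, 306 without WT replicate 2, 892 and 840 without KO replicate 1 and 2, and 8121 and 8147 without MUT replicate 1 and 2. After rescaling it was 83 and 34 without WT replicate 1 and 2, 311 and 310 without KO replicate 1 and 2, and 1737 and 1768 without MUT replicate 1 and 2. Of the 30 lists with enough members, 5 passed the camera test in KO, the risk locus among them. Androgen-repressed genes lay above the other genes (adjusted p = 0.000416, and 0.990 with an estimated correlation), with 4 risen and 3 fallen of 14 (5 and 4 when adjusted over the list alone), UGT2B15, UGT2B10 and DDC among the former and PRUNE2, a suppressor of cell migration, among the latter (adjusted p = 0.0626 after rescaling). Their median was -0.63 although their mean was 0.45, and after rescaling the list did not pass (adjusted p = 0.179), nor with quantile normalization (0.234), nor as deposited without KO replicate 1 (0.058) or 2 (0.0559). Neuroendocrine markers lay higher (adjusted p = 0.00129, median 0.40), with adjusted p = 0.990 with an estimated correlation, and 0.320 after rescaling. After rescaling 7 of their 13 tested members rose and 0 fell (adjusted p = 5.51e-05; 8 and 2 when adjusted over the list alone), with SNAP25 and CELF3, a synaptic and an RNA-binding protein, at 1.59 and 1.32. As deposited 0 rose and 2 fell, also adjusted over the list alone. CHGA, the granule protein chromogranin A, fell from 3.31 ± 1.58 to 0.446 ± 0.0904 TPM (log2 fold change -1.52). After median-ratio rescaling its fold change was -1.07 and did not pass (adjusted p = 0.0862), but in protein-coding values it passed (-1.73, adjusted p = 0.0259).

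Cytoplasmic ribosomal proteins lay above the other genes in KO (adjusted p = 0.00217 as deposited, 3.96e-06 rescaled), although their deposited median was -0.24. These were 0.990 and 0.957 with an estimated correlation. RPS29 rose from 678.4 ± 39.1 to 1708.9 ± 52.3 TPM, as the only 1 of 78 members that passed (0 when adjusted over the list alone; 2 rose after rescaling, 1 when adjusted over the list alone). Without WT replicate 2 the list did not pass (adjusted p = 0.0763), and the deposited call of RPS29 ended without any single WT or KO library (0.327 to 0.525). Genes of the unfolded protein response and amino acid starvation also lay higher (adjusted p = 0.00451, median -0.16; rescaled adjusted p = 2.26e-05, median 0.42), with 0.990 and 0.479 with an estimated correlation. As deposited 1 of 39 rose and 2 fell, 0 and 2 when adjusted over the list alone, and after rescaling 6 rose and 2 fell, or 10 and 2. ATF5, a stress-induced transcription factor, rose from 7.01 ± 0.399 to 20.8 ± 2.95 TPM, while SLC7A5 and SLC3A2, the subunits of the large neutral amino acid transporter, fell from 564.6 ± 30.2 to 38.8 ± 21.2 TPM and from 238.3 ± 62.0 to 51.0 ± 14.3 TPM. The deposited call of ATF5 ended without any single WT or KO library (adjusted p from 0.376 to 0.755), and that of SLC3A2 without WT replicate 1 (0.0888), WT replicate 2 (0.364) or KO replicate 2 (0.191). Without WT replicate 1 the list did not pass (adjusted p = 0.149).

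After rescaling, 2 further lists passed in KO, both lower, MYC targets with ribosome biogenesis (adjusted p = 0.000536, with 0 of 50 members passing singly, also adjusted over the list alone) and epithelial junction genes (adjusted p = 0.0184, with 1 of 32 fallen, 6 when adjusted over the list alone). Their adjusted p were 0.957 and 0.479 with an estimated correlation.

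In MUT minus WT the largest increase of a protein-coding gene was that of ESPN, an actin-bundling protein of microvilli, which rose from 1.07 ± 0.0295 to 89.9 ± 32.9 TPM (SD, n = 2; log2 fold change 5.41, SE 0.48, adjusted p = 2.2e-11). SLC6A19, a neutral amino acid transporter, CACNA1H, a T-type calcium channel, MUC19, a gel-forming mucin, and TMEFF2, a transmembrane protein of prostate and brain, rose by 2.79, 2.56, 2.16 and 2.09. SNORA23, a guide RNA for pseudouridylation, measured 55.4 and 82.6 TPM in WT and 293.1 and 1940.0 TPM in MUT, and SCARNA5, a Cajal body RNA, rose by 2.37. TMEFF2 did not pass without WT replicate 2 (adjusted p = 0.0719), nor, after rescaling, SLC6A19 without WT replicate 1 or 2 (0.180 and 0.164) or CACNA1H (0.0933 and 0.0908). ECM1 and ANXA2 were again nearly absent, with 0.170 ± 0.127 and 0.265 ± 0.163 TPM, and PMEPA1 fell to 7.90 ± 6.89 TPM. ANKRD30BL, an ankyrin repeat gene, measured 243.5 and 172.7 TPM in WT and was listed at 0 in both MUT libraries. HBE1, the embryonic globin, and SSX3, a cancer-testis antigen, were at 0 there as well, against 38.9 and 34.7 TPM and 38.0 and 25.5 TPM in WT. The microRNA gene MIR663A measured 3518.7 and 3028.7 TPM in WT, 180.4 and 184.2 TPM in KO, and 0.44 and 0 TPM in MUT.

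SLC7A5 fell to 16.2 ± 3.74 TPM in MUT (log2 fold change -5.06, SE 0.50, adjusted p = 3.2e-10) and SLC3A2 to 42.0 ± 22.6 TPM. Among the androgen-induced genes 50 of 68 fell and 0 rose, and 53 fell when adjusted over the list alone, but after rescaling 10 fell and 2 rose, 11 and 2 when adjusted over the list alone. KRT19, PMEPA1, ELL2, an elongation factor, and the linker histone H1F0 had log2 fold changes of -4.53, -4.73, -3.21 and -2.96, and all passed after rescaling as well. The list did not pass the camera test (adjusted p = 0.232). Of the prostate lineage transcription factors 17 of 22 fell and 0 rose, as they did when adjusted over the list alone, and after rescaling 5 fell and 3 rose, 8 and 3 when adjusted over the list alone (list adjusted p = 0.274). FOXA1 fell to 44.3 ± 10.0 TPM (log2 fold change -2.54, rescaled -1.14 with adjusted p = 0.0368), GATA2 to 13.3 ± 5.82 TPM, TRPS1 to 4.07 ± 2.06 TPM and the nuclear receptor NR2F2 to 0.895 ± 0.403 TPM. MYC (26.6 ± 6.37 TPM) fell as deposited, by 2.16, but did not pass after rescaling (adjusted p = 0.0981). Without WT replicate 1 or 2 the deposited call of MYC ended too (0.107 and 0.0566). After rescaling the call of FOXA1 ended without WT replicate 1 (0.2498) or 2 (0.130), KO replicate 1 (0.0696) or 2 (0.069), or MUT replicate 2 (0.0528), and that of GATA2 without WT replicate 2 (0.0659).

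As deposited 10629 genes passed in MUT minus WT, 118 higher and 10511 lower, and after rescaling 2007 passed, 679 higher and 1328 lower; 1427 passed both ways in the same direction. The deposited count was 1032 and 1298 without WT replicate 1 and 2, 5688 and 5697 without KO replicate 1 and 2, 9036 without MUT replicate 1 and 15238 without MUT replicate 2. Without WT replicate 1 and 2 the rescaled count was 247 and 251. Of the lower genes 132 as deposited and 115 after rescaling had an annotated length of up to 166 nt and were at 0 in both MUT libraries. Among all 5741 genes of that length 206 and 262 were above 0 in the WT libraries, 60 and 68 in the KO libraries and 5 and 6 in the MUT libraries, so these zeros follow length and are not read as a fall in the cells.

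All 13 mitochondrially encoded genes fell in MUT, also adjusted over the list alone (list adjusted p = 4.13e-08, and 0.995 with an estimated correlation). MT-ND4, a subunit of respiratory complex I, went from 7052.7 ± 1294.6 to 1006.3 ± 537.8 TPM and MT-ATP6, of the ATP synthase, from 8401.9 ± 1428.6 to 1465.0 ± 763.6 TPM. After rescaling 0 of the 13 passed, also adjusted over the list alone, and the list did not (camera adjusted p = 0.287), although its median was still -0.82. As deposited the list did not pass without MUT replicate 2. The 2 MUT libraries differed here: the rescaled log2 fold change of MT-CO2 was -2.33 without MUT replicate 1 and 0.0816 without MUT replicate 2. Of 78 cytoplasmic ribosomal proteins 66 fell and 0 rose as deposited, and 67 fell when adjusted over the list alone (list adjusted p = 0.00799, and 0.995 with an estimated correlation), but 3 fell and 2 rose after rescaling, also adjusted over the list alone (adjusted p = 0.712, direction up), and without MUT replicate 2 the rescaled list lay higher (0.00169). RPS28, RPS26 and RPL22 fell under both, with log2 fold changes of -3.16, -2.93 and -2.72 as deposited and -1.76, -1.53 and -1.33 rescaled. As deposited the ribosomal list also did not pass without WT replicate 1 (0.0561), KO replicate 1 (0.1497) or KO replicate 2 (0.142), with a minimum of 5 TPM (0.218), or with only the compared groups (0.146).

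Epithelial junction genes fell in MUT (29 of 32 as deposited, 30 when adjusted over the list alone; after rescaling 4, or 7 when adjusted over the list alone; list adjusted p = 0.0187 and 0.00348 rescaled, with 0.995 and 0.405 with an estimated correlation). DSC2 and DSP, of desmosomes, had log2 fold changes of -2.72 and -2.18, and DSP did not pass without WT replicate 1 (adjusted p = 0.0882). As deposited the list did not pass without WT replicate 2 (adjusted p = 0.131), KO replicate 1 (0.203) or KO replicate 2 (0.195), with a minimum of 5 TPM (0.217), or with only the compared groups (0.171). Genes of the unfolded protein response and amino acid starvation lay above the other genes (adjusted p = 0.000646, median -0.51; rescaled adjusted p = 1.59e-07, median 0.72), with 0.995 and 0.405 with an estimated correlation. After rescaling 14 of 39 rose and 2 fell (19 and 2 when adjusted over the list alone), the latter SLC7A5 and SLC3A2, whereas as deposited 0 rose and 8 fell (5 when adjusted over the list alone). Without WT replicate 1 the deposited list result had an adjusted p of 0.0558, and without a filter on low values 0.293. Neuroendocrine markers lay higher too (adjusted p = 0.000555, median -0.12; rescaled 0.000414, median 1.03; 0.995 and 0.405 with an estimated correlation), with 7 of 13 risen and 0 fallen after rescaling, 9 and 1 when adjusted over the list alone. As deposited 1 rose and 3 fell, 0 and 2 when adjusted over the list alone; SEZ6, a neuronal membrane protein, rose from 3.08 ± 0.263 to 8.68 ± 6.14 TPM, a call that leaving out any library but MUT replicate 1 ended (adjusted p from 0.114 to 0.262), and CHGA fell to 0.240 ± 0.0566 TPM, a call that rescaling ended (adjusted p = 0.0670).

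Nuclear-encoded oxidative phosphorylation genes lay higher in MUT only after rescaling (adjusted p = 1.69e-06, and 0.257 as deposited), with 16 of 77 risen and 2 fallen, 23 and 4 when adjusted over the list alone. The adjusted p was 0.866 with an estimated correlation. As deposited 33 of them fell and 0 rose, 22 and 0 when adjusted over the list alone. Also only after rescaling, p53 targets (adjusted p = 0.0422) and histone genes (0.0422) lay higher and basal prostate markers lower (0.0453), with 0.866, 0.916 and 0.866 with an estimated correlation.

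**Figure D3:**
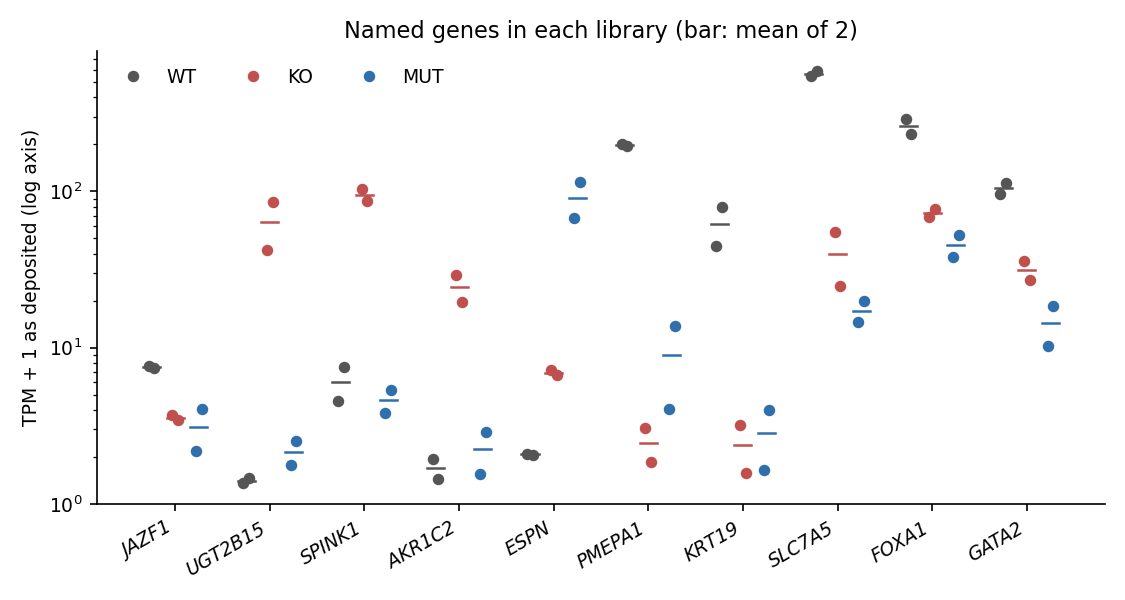
Points give TPM + 1 as deposited, on a log axis, for 10 of the named genes in each library, with a bar at the mean of the 2 libraries of a group. UGT2B15, SPINK1 and AKR1C2 stand high in KO, ESPN in MUT, and PMEPA1, KRT19 and SLC7A5 are lower in both than in WT.

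Between the 2 edited lines, ESPN was higher in MUT by 3.67 (SE 0.48, adjusted p = 1.15e-06), S100P, a calcium-binding protein, by 4.01 and SLFN11, a mediator of the response to DNA damage, by 3.94. S100P measured 57.1 and 108.8 TPM in WT, 3.89 and 5.64 TPM in KO and 39.0 and 210.5 TPM in MUT. UGT2B15 was lower in MUT by a log2 fold change of -4.83, NEFH, a neurofilament subunit, of -3.57 and HAVCR1, a cell surface receptor, of -3.33. These 6 passed after rescaling as well. The sample labels give no batch and the MUT values alone were deposited with 2 decimals, so a difference between MUT and the other groups in sequencing or processing could not be told from one of the cells. With only the compared groups in the fit S100P and SLFN11 did not pass (adjusted p = 0.061 and 0.0738). In all 992 genes passed, 90 higher and 902 lower in MUT, and after rescaling 758 passed, 280 higher and 478 lower. Both ways 521 passed in the same direction. With only the compared groups in the fit, the rescaled count was 41. The deposited count was 474 and 467 without WT replicate 1 and 2, 304 and 331 without KO replicate 1 and 2, 1144 without MUT replicate 1 and 11586 without MUT replicate 2, and 218 with only the compared groups. After rescaling it was 297 and 285 without WT replicate 1 and 2, 160 and 158 without KO replicate 1 and 2, and 1195 without MUT replicate 2.

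Of the lists, 6 passed in MUT minus KO, each with adjusted p = 0.951 with an estimated correlation. Ribosomal proteins lay lower (adjusted p = 9.83e-15, 26 of 78 fallen, 59 when adjusted over the list alone; rescaled 0.000256, 3 fallen, also adjusted over the list alone), and so did mitochondrially encoded genes (3.95e-09, 8 of 13 fallen, 12 when adjusted over the list alone; rescaled 0.212, 0 fallen either way). Androgen-repressed genes (0.0198, 5 of 14 fallen, 6 when adjusted over the list alone, among them UGT2B15; rescaled 0.142) and basal prostate markers (0.0317, 2 of 7 fallen, 5 when adjusted over the list alone; rescaled 0.0167, 0 fallen, 4 when adjusted over the list alone) lay lower. Replication-dependent histone genes lay higher (0.000148, median -0.08; rescaled 0.000360, median 0.68), with 1 of 41 fallen as deposited, 0 when adjusted over the list alone, and 1 risen after rescaling, also adjusted over the list alone. The fibroblast and endothelial markers lay higher (0.0308, rescaled 0.0872), with 6 tested members of which 0 passed. The ribosomal, basal and histone results after rescaling had adjusted p = 0.801, 0.784 and 0.801 with an estimated correlation. After rescaling the ribosomal result ended without MUT replicate 2 (adjusted p = 0.0774), the basal one without KO replicate 1 (0.0507) or MUT replicate 1 (0.0899), and the histone one without KO replicate 1 (0.0667) or MUT replicate 1 (0.589). After rescaling, MYC targets (0.000814), oxidative phosphorylation (0.000256), G2 and M phase genes (0.0167) and p53 targets (0.0423) lay higher in MUT than in KO, with 0.784, 0.784, 0.801 and 0.784 with an estimated correlation. Leaving out MUT replicate 2 ended the result for the mitochondrial (adjusted p = 0.924), androgen-repressed (0.924) and basal (0.669) lists, and leaving out MUT replicate 1 that for the histone (0.609), androgen-repressed (0.655), basal (0.196) and fibroblast and endothelial (0.393) lists. Leaving out KO replicate 1 ended the histone (0.271), androgen-repressed (0.130) and basal (0.0987) results, and leaving out KO replicate 2 the androgen-repressed (0.146) and fibroblast and endothelial (0.458) ones. The androgen-repressed result also ended with pseudocount 0.1 (0.218), no filter on low values (0.193), quantile normalization (0.135) and only the compared groups (0.424). Having no filter ended the histone (0.0582) and fibroblast and endothelial (0.156) results, and quantile normalization the latter (0.0776).

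KO and MUT shared many of their differences from WT. PMEPA1, ECM1, ANXA2, KRT19 and SLC7A5 fell in both and ESPN, IGSF9B, an adhesion protein of the immunoglobulin family, and SCARNA5 rose in both, as deposited and rescaled. In the deposited values 25 genes were higher and 1381 lower in both, where 0.949 and 876.5 were expected from the counts of calls. After rescaling 173 were higher and 531 lower in both, where 16.1 and 54.5 were expected, and 13 passed in opposite directions. Genes of up to 166 nt at 0 in both MUT libraries made up 116 of those lower in both as deposited and 95 after rescaling. The fold changes of the 2 comparisons correlated across genes with Pearson's r = 0.66 after rescaling, and simulated unchanged groups set against the same WT libraries gave 0.50; genes are not independent replicates. The covariance was 0.343, against 0.0372 in the simulations, but the share of genes with the same sign was 66.8%, against 66.7% in the simulations; as deposited it was 88.4%. With 2 WT libraries the controls cannot be divided between the comparisons. ESPN did not pass in KO as deposited without any single WT or KO library (adjusted p from 0.2503 to 0.519), nor IGSF9B in KO and MUT without WT replicate 1 (0.0789 and 0.0633). SCARNA5 did not pass without WT replicate 1 in KO (0.255) and MUT (0.0509), nor in KO without KO replicate 1 (0.0594). The deposited overlap was 236 and 204 without WT replicate 1 and 2, 780 and 725 without KO replicate 1 and 2, and 6027 and 7659 without MUT replicate 1 and 2; the rescaled one was 56 and 24 without WT and 253 and 251 without KO replicate 1 and 2.

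Along the chromosomes, runs of neighbouring protein-coding genes lay together below or above the median gene, mostly in 1 of the edited lines. Values here are protein-coding log2 fold changes relative to the median gene, in segments whose bounds were chosen after the profiles were seen. In KO the 155 tested genes from the end of the short arm of chromosome 8 to UBE2V2 had a median shift of -0.687, with 146 below 0 and 53 fallen, a shift of -0.09 in MUT, and 0.584 in MUT minus KO. In MUT the 45 genes from the end of the short arm of chromosome 18 to ANKRD30B had a median shift of -0.968, with 43 below 0 and 30 fallen, 0.11 in KO and -1.11 in MUT minus KO. In KO the 9 genes from FAM188B to BBS9, further along the short arm of chromosome 7, had a shift of 1.13, with 0 below 0 and 4 risen. On the long arm of chromosome 7, from TMEM168 to the end, 168 genes had a shift of 0.384 in KO, and on that of chromosome 18, from CDH7 to ADNP2, 25 genes had 0.684 in MUT. The 10 genes from HBG2 to OR52D1, around the globin genes of chromosome 11, had shifts of -1.63 in KO and -4.16 in MUT. In KO 80 of 11861 windows lay below the lower limit from the shuffles (-0.801) and 80 above the upper limit (0.598). A run of 20 windows above the limit lay on chromosome 3, over MME, with a median shift of 0.57. A further such run of 18 windows lay on chromosome 11, over YAP1 (median 0.51). Another of 11 windows lay on chromosome 10, over AKR1C1, AKR1C2 and AKR1C3 (median 0.08). There 10 of 25 genes lay below the median gene, and these 3 had protein-coding log2 fold changes of 4.42, 4.90 and 4.04. The window mean of 0.682 thus rests largely on them and does not show a shift of their neighbours. Shorter runs on chromosome 4 took in UGT2B15 and UGT2B10 (medians 0.22 and 0.24), with 9 and 8 of 25 genes below the median gene. The window over HOXA, JAZF1 and CREB5 had a mean of -0.96 with 24 of 25 genes below 0. PRR15, CHN2 and SCRN1, chosen after their values were seen, lay just beyond CREB5, and the 11 genes from there to GARS had shifts of -1.16 in KO and -1.07 in MUT, with 6 fallen in each.

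**Figure D4:**
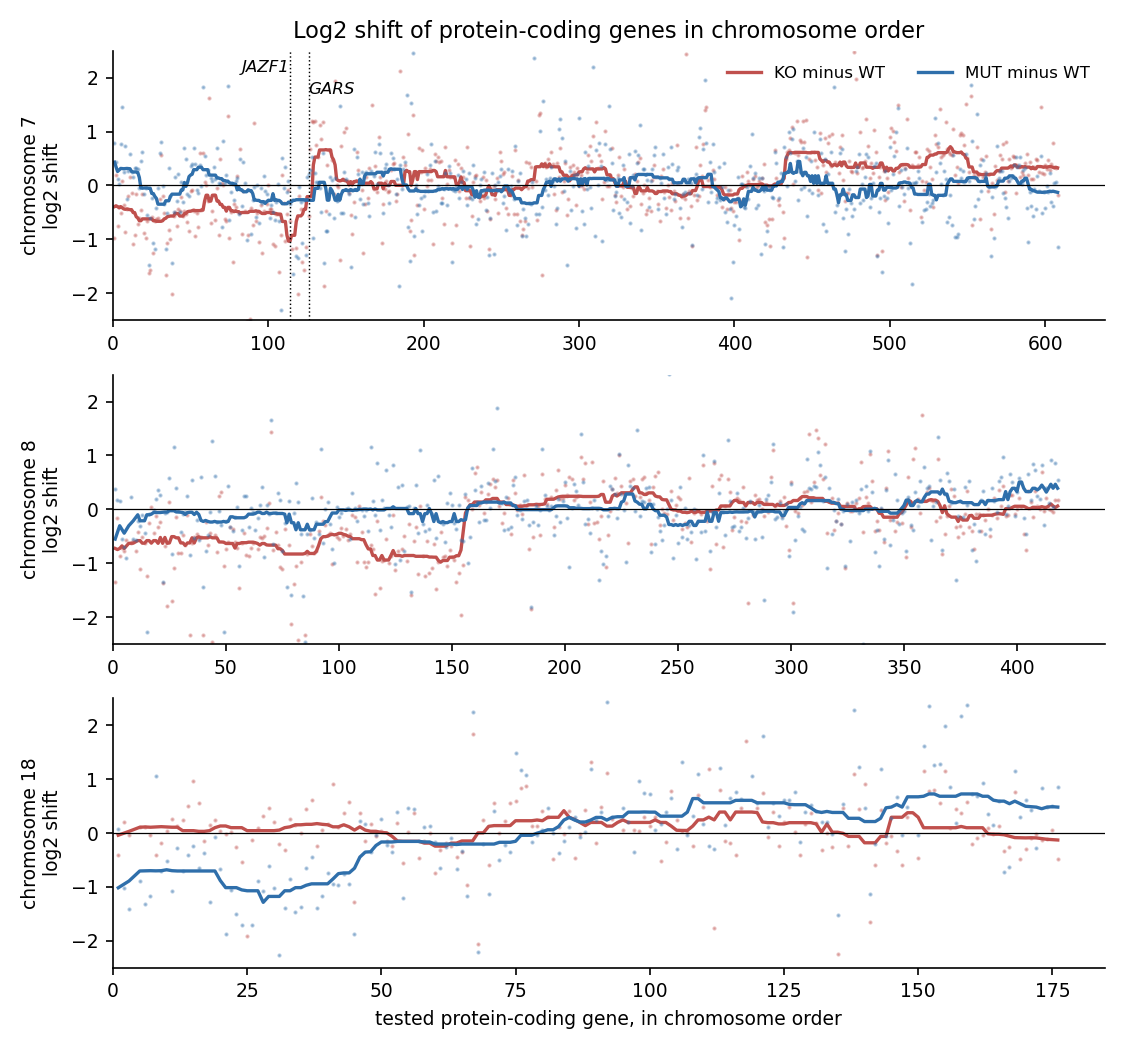
Points are shifts of protein-coding genes relative to the median gene (log2) in chromosome order for chromosomes 7, 8 and 18, and lines are running medians over 21 genes; points beyond the axis are not drawn. The KO line lies below 0 at the start of chromosomes 7 and 8, and the MUT line at the start of chromosome 18.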

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

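All median-ratio fits with 1 library left out, the compared groups alone or the block, the protein-coding values and the length correction were chosen only after the results were seen. Among the 159 results for single named genes, 3893 alternative values comprised 3069 with the same direction and side of the threshold, 671 no longer past it, 75 newly past it and 78 of the other sign, 24 of these for genes called as deposited. The unknown depth limits the low genes, whose counts cannot be recovered from TPM.

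Counts of passing genes are given in the order KO minus WT, MUT minus WT, MUT minus KO and the overlap, with the passing lists and risk locus genes where these moved. Pseudocount 0.1 gave 886 KO genes, 1 risk locus gene in KO and an overlap of 758, and pseudocount 0.5 gave 3 risk locus genes in KO. With no filter, which adds genes near 0, there were 720, 4519, 8 and 673, with 11, 13 and 13 lists and 0 and 4 risk locus genes in KO and MUT. A minimum of 5 TPM, which tests fewer genes, gave 771 in KO and an overlap of 681, 3 lists in MUT, and 3 and 8 risk locus genes. Median-ratio rescaling gave 2007 in MUT, an overlap of 704 and 0 and 2 risk locus genes, and quantile normalization 1922 in MUT, 628 in MUT minus KO, an overlap of 701 and 0 and 2. Without the variance trend there were 1012, 658 in MUT minus KO and an overlap of 890, with 1 risk locus gene in KO. With only the 2 compared groups there were 8004, 5755, 218 and 3648, with 10 lists in KO and 16 and 7 risk locus genes. Protein-coding rescaling gave 1064, 1551 and an overlap of 555, 9 lists in KO and 2 and 1 risk locus genes; the length correction gave 1575 in MUT, an overlap of 567, 8 lists in KO and 1 and 1. Median-ratio rescaling with only the 2 groups gave 1341 in MUT, 41 in MUT minus KO, an overlap of 628 and 0 and 2. An estimated correlation left 0 lists in each comparison. As deposited no list passed fry in KO (lowest adjusted p = 0.234) or MUT minus KO (0.157). In MUT some did, among them the ribosomal and risk locus lists (0.0453 each), but not the epithelial junction (0.0548) or neuroendocrine (0.404) ones. After rescaling only the risk locus, androgen-repressed (0.00563) and neuroendocrine (0.0131) lists passed fry in KO. In MUT the risk locus list passed (0.0432), and in MUT minus KO only the androgen-repressed one (0.00348). For the other moved counts the cause was not tested.

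The replicate numbers do not pair the libraries: the deviations of replicates from their group means correlated across genes at 0.05, 0.02 and 0.02 between groups. With the replicate number as a block, median-ratio rescaling gave 913, 1682, 508 and an overlap of 588, with 0 and 2 risk locus genes. The cause was not tested.

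Leaving out 1 library as deposited gave 306 to 8147 genes, 5 to 11 lists and 0 to 16 risk locus genes in KO, 1032 to 15238 genes, 3 to 15 lists and 2 to 19 risk locus genes in MUT, 304 to 11586 genes and 2 to 12 lists in MUT minus KO, and an overlap of 204 to 7659. Rescaled it gave 34 to 1768, 6 to 10 and 0 to 1 in KO, 247 to 2106, 4 to 9 and 0 to 2 in MUT, 158 to 1195 and 3 to 9 in MUT minus KO, and an overlap of 24 to 800. Leaving out a library leaves fewer degrees of freedom, and MUT replicates 1 and 2 differ most in composition.

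Signs turned for genes near the median of all genes, where rescaling removes the shift. In KO, HOXA11 was 0.0422 after quantile normalization, and HOXA10 was 0.16 after median-ratio rescaling (also with only the 2 groups or the block), 0.19 after quantile normalization, 0.10 in protein-coding values and 0.17 with the length correction. In MUT, median-ratio rescaling (also with only the 2 groups or the block) gave HOXA6 0.0378, HOXA13 0.30, TAX1BP1 0.0925, HOXB13 0.51 and HOXA10 0.46. Quantile normalization gave HOXA11 0.27, HOXA2 0.0823, HOXA6 0.0794, HOXA13 0.36, TAX1BP1 0.10, CREB5 0.0306, HOXB13 0.51 and HOXA10 0.50. Protein-coding values gave HOXA13 0.23, HOXB13 0.40 and HOXA10 0.40, and the length correction HOXA13 0.30, TAX1BP1 0.17, HOXB13 0.48 and HOXA10 0.43. The ribosomal list in MUT turned with adjusted p = 0.712 after median-ratio rescaling, 0.758 with only the 2 groups and 0.789 with the block, and it passed in the other direction after median-ratio rescaling without MUT replicate 2 (0.00169). The epithelial junction list in MUT did not pass with the block as deposited (0.0562). The basal list in MUT minus KO turned with 0.905 without a filter; the cause was not tested.

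With 1 library left out the ranges, first as deposited and then rescaled, were -1.01 to -0.46 and -0.43 to 0.15 for RPS2, -0.0514 to 0.17 and 0.52 to 0.77 for HOXB13, and -0.52 to -0.17 and 0.00137 to 0.32 for HOXA10 in KO. In MUT they were -0.89 to -0.20 and -0.28 to 0.21 for HOXA11, -1.26 to -1.04 and -0.33 to 0.40 for HOXA6, -1.52 to 0.19 and -0.25 to 0.85 for HOXA13, -2.14 to -0.77 and -0.43 to 0.21 for HIBADH, -1.92 to -0.64 and 0.00494 to 0.18 for TAX1BP1, -1.17 to -0.53 and 0.28 to 0.73 for HOXB13, -3.16 to -1.90 and -2.33 to 0.0816 for MT-CO2, and -0.97 to -0.45 and 0.25 to 0.67 for HOXA10. HOXA10 in both, and TAX1BP1 and HOXB13 in MUT, thus turned with the scaling and not with a library left out. Adjusted p ranged from 0.000305 to 0.1497 and 0.00169 to 0.755 for ribosomal and from 1.32e-16 to 0.906 and 8.30e-08 to 0.385 for mitochondrial genes in MUT. In MUT minus KO it ranged from 0.00139 to 0.924 and 0.111 to 0.505 for androgen-repressed, from 1.57e-13 to 0.924 and 2.48e-09 to 0.379 for mitochondrial, and from 2.1e-28 to 0.609 and 4.35e-20 to 0.589 for histone genes. The cause was not tested.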

Other observations

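Each test of an explanation in this part was set up only after the results were seen, as were the protein-coding values, the chromosome segments and all values by RNA length or class; the list test, the overlap with its simulations and the median-ratio and quantile scalings were planned. Among structured RNAs annotated at under 200 nt 71 of 112 fell in KO and 0 rose after median-ratio rescaling, while of 9 annotated at 250 to 400 nt 5 rose and 1 fell. The 5 that rose were all Cajal body RNAs, which make up 6 of the 9. The lengths were compared in 132 genes of the snRNA, snoRNA and Cajal body classes with RMRP, 7SK and the Y RNAs, without RPPH1 and without the 7SL genes, of which 1 of 115 rose and 5 fell in KO after rescaling. In KO the U5 spliceosomal RNAs fell in all 7 tested copies as deposited and in 6 after rescaling, mitochondrial tRNAs in all 10 and in 8, and box H/ACA RNAs, which guide pseudouridylation, in 51 and 41 of 63. Of 14 Cajal body RNAs 4 rose and 4 fell in KO as deposited, and 5 rose and 4 fell after rescaling. The MUT values ended at a length: all 103 of these genes of up to 166 nt were at 0 in both libraries, against 4 and 2 at 0 in the WT libraries and 63 and 61 in the KO libraries, and the shortest above 0 had 182 nt. U1 RNAs, at a sum of 11498.3 TPM in WT, were at 0 in MUT with the U5 RNAs, the Y RNAs and the mitochondrial tRNAs, and without read counts such zeros are not read as a lower level of these RNAs.

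The first pattern is that more genes were lower than higher against WT, with more TPM on structured RNAs of 250 to 400 nt. The larger share of small structured RNAs could account for most of the lower median. In KO replicate 1 and 2 and MUT replicate 1 and 2 it predicts log2 shifts of -0.521, -0.581, -1.69 and -0.983. The 10752 other genes had medians of -0.618, -0.644, -2.02 and -0.869. The largest difference was -0.326, in MUT replicate 1. There the prediction lay just inside the upper quartile (-1.66), a bound set after these values were seen. Because TPM have a fixed sum, the total of the other genes must fall by the predicted amount. The closeness of the medians is thus largely arithmetic and does not test the explanation. What raised the share is left open, as TPM do not separate a rise of these RNAs from a fall of all others, and the balance that remains depends on the scaling, with 1117 lower and 434 higher protein-coding calls in MUT in protein-coding values (698 and 366 in KO) but 605 and 593 (388 and 410 in KO) with quantile normalization. A lower retention of RNAs under 200 nt in the KO libraries could give the share fallen by length, though class and length largely coincide. The two-sided exact Fisher test gave p = 0.00306, and 0.00733 with no upper length limit and no Cajal body RNAs. It counts genes as independent, but near-identical copies, as of U1 RNA, share reads, and all genes come from the same libraries. Its p-values thus do not measure the spread between libraries. In MUT the zeros in all 103 genes of up to 166 nt void that test, so a lower retention, a length limit in processing and a lower level in the cells cannot be told apart, and an effect of the edits was not tested in either line.

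The second pattern is the lower level of the risk locus genes in KO. At the preset correlation the composition of the libraries does not account for it, since the list stayed lower after median-ratio rescaling (adjusted p = 0.000339, or 0.320 with an estimated correlation). Nor is it a change of JAZF1 alone, as 8 other genes of the list had a lower rescaled fold change. A lower level of a wider part of the chromosome arm is a candidate explanation: the other 112 protein-coding genes from the end of the short arm to GARS had a median shift of -0.508, with 95 below 0, against -0.60 for the 14 of the list, though 9 genes further along the arm, from FAM188B to BBS9, lay higher (1.13). In MUT, labelled as changed at the same variant, these 112 genes had a median shift of 0.00072, with 56 below 0. The 14 of the list had -0.282 there, with 10 below 0. In KO the 155 genes on chromosome 8, which are not near the edited site, also lay lower (-0.687). A change in copy number could give such runs. On chromosome 7 these data cannot separate it from an effect of the KO edit on nearby genes, which was not tested. The KO and MUT edits differ in kind, so the MUT values do not settle this.

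The third pattern is the set of genes that moved the same way in KO and MUT. Chance values of the shared WT libraries alone would give the simulated covariance, and the covariance after rescaling was above it by 0.306. The share of genes with the same sign (66.8%) was close to the simulated 66.7%, though 88.4% as deposited, and the excess was 0.2902 in protein-coding values, so the short RNAs at 0 in MUT do not make it up. Chromosome Y transcripts themselves are a small part of the set, as 381 of the 391 protein-coding genes lower in both lie elsewhere. Only 10 chromosome Y genes were tested, all lower in both, so no more than 10 could lie there. Whether a loss of that chromosome also changed other genes was not tested. The first principal component after rescaling held 50.2% of the variance and put WT at the low end, MUT at the high end and KO between them. This order of the groups does not test for a difference of WT alone. A WT difference that is not the edit could give the same set. Such a difference cannot be told apart from an effect shared by the edits, because every edited library is compared with the same 2 WT libraries.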
